A study of Homo sapiens with 8 samples.

How the data were processed

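RNA from HaCaT keratinocytes was labelled with biotin and hybridised to Affymetrix human arrays, 1 array for each of 8 samples, per the labels' protocols. The deposited table holds 1 intensity per probe set on a linear scale, made with MAS5 5.0 per the submitters' processing notes. The values show that each array had been scaled to a 2% trimmed mean of about 100, found here from the deposited table. Its 54675 probe sets include 62 control probe sets, and no columns of the 8 were identical. Detection calls were not used here, so a dim signal was handled by a floor and a filter.

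Groups were taken from the sample titles and from the label field on TGF-beta stimulation, which match each other. A further label field gives the opposite TGF-beta state for the 6 adenovirus samples and was not used. The vector, siRNA and TGF-beta state give 8 groups of 1 array. As nothing separates cultures within a group, p-values measure only the spread between these arrays, which may be technical.

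Signals were scaled again to a trimmed mean of 100, set to at least 20 and put on the log2 scale. The floor makes a change of a dim gene smaller than it was. Probe sets were named through the platform annotation given for them, with symbols updated through gene identifiers in RefSeq's gene table, whose coordinates were not used. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here; only the first were used, and 41043 of them were matched to the gene table. Each of 19740 genes was represented by its single-symbol probe set with the highest mean log2 signal, and 10511 genes had at least 2 probe sets. No coordinates are given, since the sources used here name no genome build. Some members of the gene lists had no named probe set here and were not analysed here, and 1 result planned for the siRNA arrays is not reported here.

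The 6 adenovirus arrays were fitted with limma 3.58.1 in R 4.3.3 by an additive model of vector and TGF-beta, for genes with a scaled signal of at least 50 on at least 2 arrays, with a trended eBayes prior and Benjamini-Hochberg adjustment. The fit leaves 2 residual degrees of freedom, which hold the interaction of vector and TGF-beta as well as noise. A gene whose effect differs across the other factor thus has a larger residual but can still pass. The prior had 8.73 degrees of freedom and the median residual SD was 0.172 on the log2 scale. An adjusted p under 0.05 was called a rise or a fall. Single pairs of arrays were described by log2 ratios and by the genes at least 2-fold apart with a scaled signal of 50 on 1 array of the pair, with no test, and the 2 differences of TGF-beta response likewise with a difference of at least 1. Gene signals of the siRNA arrays were compared only with each other, while control probe sets were also compared with those of the adenovirus arrays.

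The 37 gene lists were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Of them 33 had at least 3 tested genes; the lists of fibroblast, melanocyte, leukocyte and endothelial markers, 4 in all, had fewer and were not tested. In the fits of the 6 arrays these 4 lists had as measured members COL1A1 and COL3A1, which are also in the matrix list, and MITF; COL3A1 was at the floor on the LacZ and HRAS G12V arrays. On the siRNA arrays HLA-DRA was the 1 measured leukocyte marker, and 0 endothelial markers were measured on any array. The averaged contrasts were tested with camera, with a preset inter-gene correlation of 0.01 and again with an estimated one. For pairs and differences the median of a list was placed among those of 10000 random lists of the same size matched on mean expression, which describes these arrays and is not a test.

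The rule for named genes took HRAS; for each contrast up to 8 genes with the largest rise and 8 with the largest fall among genes at least 2-fold apart the same way in every pair of arrays, with a signal of at least 100 on the higher side and above the floor on both; up to 4 members of each list with the largest change; and the 6 largest differences of TGF-beta response in each direction among genes with a signal of at least 100 on at least 1 of the 4 arrays and above the floor on all 4. For the comparison of the RAS vectors with each other only HRAS and list members were taken. Genes on the Y chromosome and XIST were left out.

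The fit was tested on simulated data of 8981 genes with 200 changed genes. For the TGF-beta contrast it recovered 95.5% of the genes changed by 1 on the log2 scale and 41.5% of those changed by 0.5, and 6.4% and 7.8% of its calls were false. For HRAS G12V against LacZ it recovered 86% and 15%, with 3.4% and 9.1% of calls false, and for HRAS N116Y against LacZ 89.5% and 1%, with 3.8% and 33.3% false, the last being 1 false call. In 4 of these 6 settings the share of false calls was thus above the 5% that the threshold aims at. Each setting was a single draw, so these shares carry the noise of that draw. Both contrasts with LacZ have the same design and median SE (0.172), so 15% against 1% does not set them apart. The 200 changed genes are far fewer than the data's calls for TGF-beta. The simulated noise was drawn independently for each gene, and the simulated effects held no interaction of vector and TGF-beta. These shares thus check the fit and may not hold for the real arrays. The alternatives were quantile normalization, floors of 10 and 50, no filter or a filter of 100 on dim genes, the mean of all probe sets of a gene, eBayes without a trend, leaving out the 2 arrays of a vector in turn, fits of the 4 arrays of 2 vectors and TGF-beta with no vector block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.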

Results

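Gene expression was measured in HaCaT cells, an immortalized line of human epidermal keratinocytes, on 8 Affymetrix arrays of 54675 probe sets each. In 6 of the groups, cells carried an adenoviral vector for LacZ (the control), HRAS G12V (a constitutively active RAS) or HRAS N116Y (a dominant negative RAS), each without or with 5 ng/ml TGF-beta3 for 24 h. The other 2 groups were transfected with a control siRNA or an siRNA against p53 and received no TGF-beta. Each group held 1 array, so no value below has a replicate within its group, and the number of arrays limits the precision throughout. The 2% trimmed mean of the signal was about 100 on each of the 8 arrays, and between 28.0% and 29.9% of the probe sets reached a scaled signal of 50.

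The siRNA arrays stood apart from the adenovirus arrays in a quality measure. The ratio of the 3' to the 5' actin probe set was 3.68 with control siRNA and 4.01 with p53 siRNA, against 1.16 to 1.39 on the 6 adenovirus arrays. The same ratio for GAPDH lay closer, at 1.07 and 1.04 against 0.93 to 0.98. Gene signals of the siRNA arrays were therefore not compared with those of the adenovirus arrays. The arrays are named by their titles and the TGF-beta field of their labels, because another label field gives the opposite TGF-beta state for all 6 adenovirus arrays.

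The first question was what TGF-beta3 does in these keratinocytes. MMP9, which encodes a gelatinase, rose 29.2-fold on average over the 3 vectors (log2 change 4.87 ± 0.17 SE, adjusted p = 6.22e-08). FN1, the matrix protein fibronectin, rose 15.7-fold, SERPINE2, a serine protease inhibitor, 9.52-fold, and PMEPA1, a feedback inhibitor of TGF-beta signalling, 8.1-fold. NEDD9, SEMA3C, SPRR1B and ADAMTS6 rose between 6.4-fold and 7.34-fold. KRT4, an epithelial keratin, fell 6.56-fold (log2 change -2.71 ± 0.13 SE, adjusted p = 8.11e-07), and PEG10, ASS1 (argininosuccinate synthase), PTGES (prostaglandin E synthase), ZNF367, SCEL, FOXQ1 and STS fell between 4.1-fold and 5.77-fold. These 16 genes changed at least 2-fold the same way in all 3 vectors. HRAS had a log2 change of -0.23 (adjusted p = 0.266).

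Of 29 tested genes known to be induced by TGF-beta through SMAD proteins, 25 rose and 0 fell, and 27 rose when adjusted over the list alone. LTBP2, a member of the latent TGF-beta binding protein family, rose by 3.36 on the log2 scale and CCN2, a matricellular growth factor, by 2.73. These 2 estimates depend on the floor, because 1 of the 3 untreated signals of each gene was below 20 and was set to 20, and so do those of COL5A1, KRT16, MMP10 and WNT5B given below, with 1 such signal for the first 2 genes and 3 for the others. Of 9 growth genes repressed by TGF-beta in keratinocytes, 8 fell, among them CDC25A, ID2, CCNA2 and ID1 with log2 changes from -1.56 to -1.41. The same number, 8, fell when adjusted over the list alone. All 40 tested genes of S phase and mitosis fell, also when adjusted over the list alone, with a median log2 change of -1.36; ORC1 fell by 1.86, BUB1B by 1.83, PLK1 by 1.80 and MKI67 by 1.73. The CDK inhibitors CDKN2B and CDKN1A rose by 2.54 and 2.43 and CDKN2A by 0.85, while CDKN1B had a log2 change of -0.15 (adjusted p = 0.31).

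Of 18 extracellular matrix genes 12 rose and 1 fell, with TGFBI at 2.59, COL1A1 at 2.35 and COL5A1 at 2.32 on the log2 scale. Of 9 integrin subunits 7 rose, led by ITGA5 (2.05) and ITGAV (1.07). Of 17 proteases and plasminogen system genes 12 rose and 4 fell; MMP10 rose by 4.98, MMP1 by 2.56 and PLAU (urokinase) by 1.88. Of 10 mesenchymal genes 7 rose, including TAGLN (1.92), TPM1 (1.76) and SNAI2 (1.63), and 1 fell. Of 20 epithelial junction genes 9 rose, DSC2 by 1.16 and JUP by 0.94 among them, and 0 fell in limma's test. Adjusted over the list alone, these counts were 12 up and 1 down, 7 up, 12 up and 4 down, 7 up and 1 down, and 10 up.

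Members of several other lists changed with TGF-beta3, while tests of the lists as a whole are given below. Of 13 inflammatory cytokine genes 10 rose and 1 fell, with PTGS2 (cyclooxygenase-2) at 2.18, CCL2 at 1.85, IL6 at 1.76 and IL1A at 1.48. Of 12 genes of cholesterol synthesis and uptake 10 rose, HMGCS1 by 1.39 and INSIG1 by 1.10. Of 16 interferon-stimulated genes 8 fell and 2 rose. IFIT3 fell by 1.41, IFIT1 by 1.34 and RSAD2 by 1.21, while IRF9 rose by 1.26. The fall of IFIT3 was hardly seen with HRAS N116Y, as given below. Of 13 YAP and TAZ target genes 8 rose and 1 fell, of 12 BMP and WNT genes 9 rose (INHBA by 2.55, WNT5B by 2.40) and 2 fell (BMP7 by 1.47), of 5 histone genes 4 rose and of 10 immediate early and heat-shock genes 6 rose (JUN by 1.41). Adjusted over the list alone, 10 cytokine genes rose and 1 fell, 10 cholesterol genes rose, 9 interferon-stimulated genes fell and 2 rose, 9 YAP and TAZ targets rose and 1 fell, 9 BMP and WNT genes rose and 2 fell, 4 histone genes rose and 6 immediate early genes rose.

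Lists with smaller or mixed movement were as follows. RAS-MAPK output genes had 8 up and 1 down of 19, among them EPHA4 (2.22) and EGR1 (1.43). EGR1 did not rise with HRAS N116Y, as given below. Genes linked to p63 had 10 up and 3 down of 20. Targets of wild-type p53 had 9 up (CDKN1A by 2.43, GADD45A by 1.35) and 5 down (KITLG with -1.35) of 23. Genes linked to mutant p53 had 5 up and 3 down of 14. Suprabasal differentiation genes had 5 up and 2 down of 13: SPRR1B and IVL (involucrin) rose by 2.68 and 1.37 and FLG (filaggrin) fell by 1.32. EGF receptor ligands and receptors had 3 up and 1 down of 7, TGF-beta ligands, receptors and SMADs 3 up and 3 down of 16, RAS genes and regulators 3 up and 1 down of 7, hypoxia-induced genes 5 up and 1 down of 14, endoplasmic reticulum stress genes 4 up and 2 down of 16, Notch genes 2 up and 2 down of 10 and oxidative stress genes 2 up and 1 down of 10. Basal keratins had 2 of 4 up (KRT16 by 1.65), simple keratins 2 of 5 up (KRT7 by 0.74), glycolytic enzymes 1 of 16 down, ribosomal protein genes 1 of 22 up and BCL2 family genes 0 of 9 changed. Adjusted over the list alone, the rising and falling genes numbered 8 and 2, 10 and 3, 10 and 6, 6 and 3, and 5 and 3 for the first 5 of these lists, in order, then 3 and 1, 3 and 3, 3 and 1, 7 and 1, 5 and 2, 2 and 2, 1 and 1, 2 and 0, 3 and 0, 0 and 1, 0 and 0, and 0 and 0 for the rest.

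Among markers of other cell types, MITF of melanocytes fell by 0.59 (adjusted p = 0.0232, and 0.0207 to 0.0676 over 6 alternatives, failing with no filter on dim genes), and COL1A1 of fibroblasts rose as given above.

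In all, 1466 genes rose and 1567 fell of 8981 tested (limma, additive model of vector and TGF-beta), and 345 and 336 of them changed at least 2-fold. With the correlation between genes preset, camera called 19 of 33 lists, 16 up and 3 down, and placed the SMAD-induced genes above the other genes (adjusted p = 4.27e-19) and the cell cycle genes below (adjusted p = 1.59e-26). With an estimated correlation, which leaves the test few degrees of freedom, 0 lists passed. Camera's smallest value was adjusted p = 0.309, for the SMAD-induced genes, and the cell cycle genes had 0.333. The estimated correlation was 0.006 for the SMAD-induced list, but 0.835 for the cell cycle, 0.809 for the ribosomal protein, 0.524 for the interferon and 0.399 for the cholesterol list. Where it exceeds the preset 0.01, calls with the preset, also in the contrasts below, are less firm than their p-values. The ribosomal protein list, called up with a median of 0.21, had a median of -0.052 under quantile normalization and 0.127 with the mean of all probe sets, and the MAPK, interferon, CDK inhibitor and p63 lists also lost this call in 1 or 2 of 6 alternatives. Without the HRAS G12V pair of arrays the fit called 975 rising genes, and without the vector as a block it called 953. The rule named 119 genes called in this contrast. Of these, 102 passed in every alternative of processing that kept the 6 arrays and the model, and 3 failed in most. There were 7 such alternatives, but only those in which a gene was still tested count. For some genes these were as few as 5. With the mean of all probe sets the log2 changes were smaller for SERPINE2 (1.68), NEDD9 (1.29), ADAMTS6 (1.28), KRT4 (-1.48), STS (-1.17), TPM1 (1.12), IL1A (0.75) and KRT7 (0.42), which still passed, and for CDKN2A (0.46), which did not. EGR1 passed in 5 of 7 alternatives, and IFIT3 and RSAD2 in 6 of 7. With a floor of 50 IL6 rose by 0.735, BMP7 fell by 0.85, and the dim genes LTBP2, CCN2, COL5A1, WNT5B and KRT16 rose by 2.17 to 0.78.

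**Figure D1:**
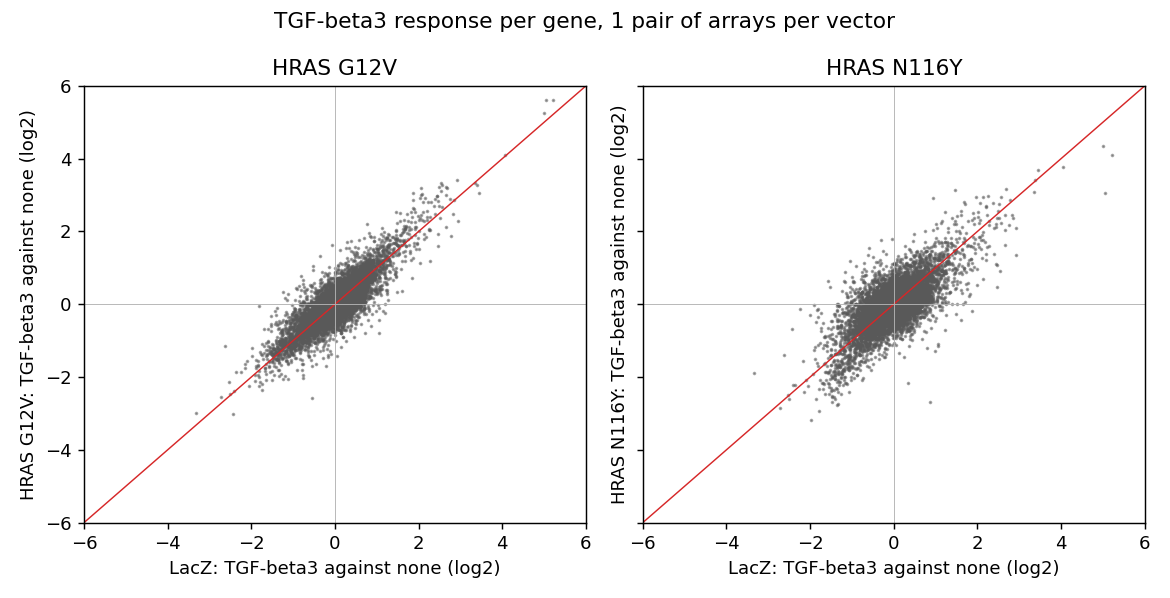
Each point is 1 of the 8981 tested genes, placed by its log2 ratio of TGF-beta3 to untreated signal in LacZ cells (x axis) and in HRAS G12V or HRAS N116Y cells (y axis), 1 pair of arrays per vector; the line marks equal responses. The Pearson correlation across genes was 0.857 for HRAS G12V and 0.713 for HRAS N116Y, whose points lie more widely about the line.

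The TGF-beta3 response was also taken within each vector. FN1 had log2 ratios of 4.06 with LacZ, 4.10 with HRAS G12V and 3.77 with HRAS N116Y, and PMEPA1 had 2.69, 3.19 and 3.17. With LacZ, 374 genes were at least 2-fold higher with TGF-beta3 and 390 lower, with HRAS G12V 492 and 404, and with HRAS N116Y 442 and 446. The SMAD-induced genes had median log2 ratios of 1.505 with LacZ, 1.80 with HRAS G12V and 1.67 with HRAS N116Y, each at percentile 100 of 10000 random lists matched on expression. Across genes, which are not independent replicates, the LacZ response correlated with the HRAS G12V response at r = 0.857 and with the HRAS N116Y response at r = 0.713, and the last 2 with each other at r = 0.699, 3 relations from separate arrays. These ratios are of 1 array to 1 array and were not tested. The mean of all probe sets of a gene gave 228, 311 and 244 genes higher in the 3 vectors.

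The second question was what active RAS changes. HRAS itself, read by 1 probe set, had lower signals on the arrays labelled HRAS G12V (108.8 untreated, 86.1 with TGF-beta3) and HRAS N116Y (67.1 and 58.1) than on the LacZ arrays (315.7 and 287.0). Where this probe set lies relative to the sequence in the vector is not given in the sources used here, so it does not check the expression of the insert. MMP7, which encodes matrilysin, fell by 1.73 on the log2 scale with HRAS G12V against LacZ (SE 0.19, adjusted p = 0.0121), HRAS by 1.64 (SE 0.18, adjusted p = 0.0121), PLAC8 by 1.35 (adjusted p = 0.0352) and IL1RAP, the accessory chain of the interleukin-1 receptor, by 0.98 (adjusted p = 0.0352); IL1RAP was named after its value was seen. CACNG4, a calcium channel subunit, had a log2 change of 1.78 (adjusted p = 0.108) and CCDC80 one of -1.22 (adjusted p = 0.0788), both at least 2-fold in both pairs of arrays but past no threshold.

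These 4 falling genes were the only ones that passed, with 0 rising, of 8981 genes tested by limma. At an unadjusted p under 0.05 there were 305 rising and 269 falling genes, 574 in all, where chance gives 449. The RAS-MAPK output genes had 0 of 19 past the threshold, and 1 that fell when adjusted over the list alone. DUSP6, an ERK phosphatase induced by ERK, had a log2 change of 0.51 (adjusted p = 0.683), EGR1 one of 0.83 (adjusted p = 0.832) and EPHA4 one of -0.76 (adjusted p = 0.514). The 40 cell cycle genes had a median of 0.20, above the other genes with a preset correlation (adjusted p = 8.63e-05) but with adjusted p = 0.783 with an estimated correlation, and 0 of them passed alone. Suprabasal differentiation genes had a median of -0.15 (adjusted p = 0.0148, and 0.783 with an estimated correlation), with ELF3 at -0.77 and KLK7 at -0.64 and 2 that fell when adjusted over the list alone. MMP7 was the member of the protease list that fell and HRAS that of the RAS list, also when adjusted over the list alone. In the other lists 0 members passed limma's test over all genes. Adjusted over the list alone, 2 SMAD-induced genes, 2 histone genes and 1 gene each of the mesenchymal, p63, CDK inhibitor and hypoxia lists fell, 1 glycolytic gene rose, and 1 cytokine gene rose and 1 fell. Camera with a preset correlation also called the ribosomal protein (median 0.22), endoplasmic reticulum stress (0.13), oxidative stress (0.17) and immediate early (0.22) lists up and the CDK inhibitors (-0.20) down, each with adjusted p = 0.783 with an estimated correlation. The ribosomal protein median was -0.013 under quantile normalization. Of these 7 lists called with a preset correlation, the cell cycle list alone passed in all 6 alternatives, and the CDK inhibitors passed in 2. Without the filter the median of the CDK inhibitors was -0.06 and that of the immediate early list 0.11, with the mean of all probe sets that of the CDK inhibitors was -0.09, and with a filter of 100 that of the endoplasmic reticulum stress list was 0.23.

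In single pairs of arrays, 15 genes were at least 2-fold higher and 20 lower with HRAS G12V against LacZ without TGF-beta3, and 22 and 30 with it. A fit of the 4 LacZ and HRAS G12V arrays, with 1 residual degree of freedom, called 107 rising and 104 falling genes. With no filter on dim genes the fit of 6 arrays called 0 genes in limma's test. Over 7 alternatives HRAS passed in 6, MMP7 in 5, and PLAC8 and IL1RAP in 1 each. The adjusted p in limma's test lay between 0.0127 and 0.398 for HRAS and MMP7, between 0.0369 and 0.814 for PLAC8 and between 0.0369 and 0.631 for IL1RAP. The log2 change of IL1RAP was -0.50 with the mean of all probe sets, and that of MMP7 was -1.27 with a floor of 50 (adjusted p = 0.261).

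**Figure D2:**
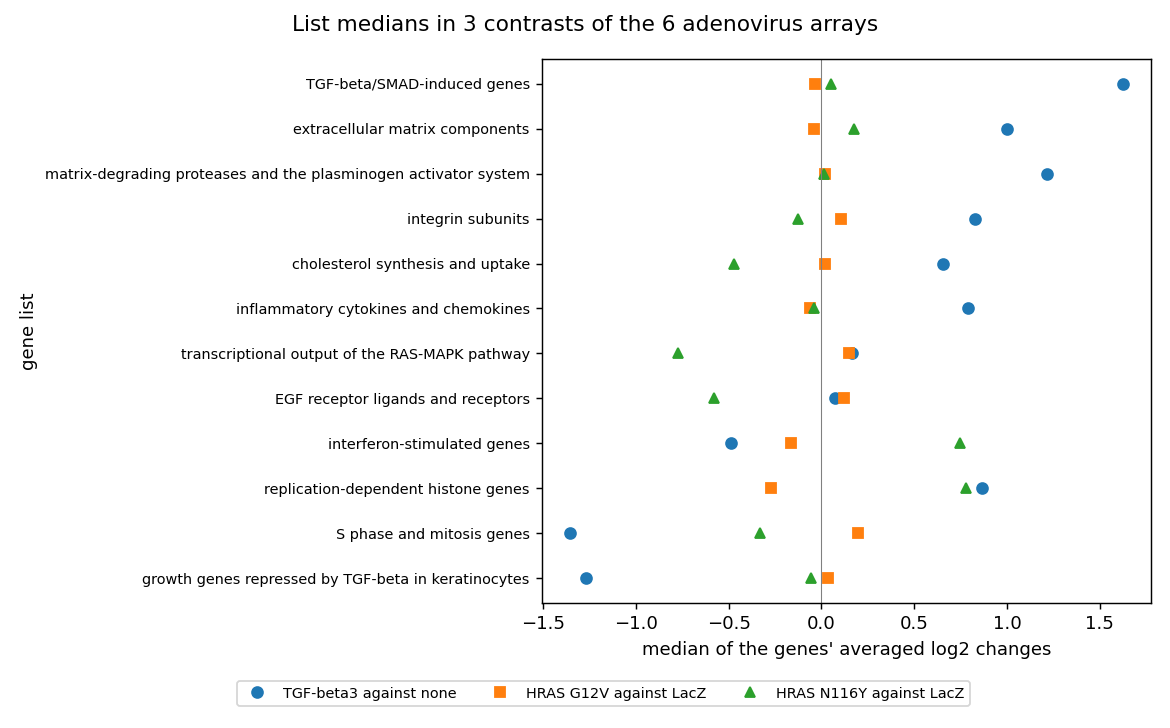
Each symbol is the median over a gene list (y axis) of the genes' log2 changes averaged in the limma fit (x axis), for TGF-beta3 against none (circles), HRAS G12V against LacZ (squares) and HRAS N116Y against LacZ (triangles). The circle of the SMAD-induced genes lies at 1.63, and the triangle of the RAS-MAPK output genes at -0.78 where the square lies at 0.15.

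The third question was what dominant negative RAS changes. The chemokine genes CCL5 and CCL2 rose by 3.27 and 3.24 on the log2 scale with HRAS N116Y against LacZ (SE 0.37 and 0.27, adjusted p = 0.00148 and adjusted p = 0.000252). TNFAIP2 rose by 2.77, CACNG4 by 2.45, the cytokine IL32 by 2.39, and TMT1A, PLAAT4 and MPPED2 by 2.37 to 2.30. Against the same LacZ arrays, CACNG4 was also at least 2-fold higher with HRAS G12V in both pairs, though past no threshold. Its rise may thus not be particular to HRAS N116Y. IL1RL1, the receptor of interleukin-33, fell by 3.24 (SE 0.22, adjusted p = 0.000103), HRAS by 2.27 (SE 0.18, adjusted p = 0.000244) and CEMIP, a hyaluronan-degrading protein, by 2.26. ANXA10, DUSP6, IL1R2 (the decoy receptor of interleukin-1), HAS2 (a hyaluronan synthase) and PTGS1 fell by 1.99 to 1.78. With the mean of all probe sets TNFAIP2 rose by 1.59 and IL1RL1, CEMIP and PTGS1 fell by 1.63, 1.29 and 1.17, each still past the threshold.

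Of 19 RAS-MAPK output genes 8 fell and 0 rose, and 10 fell and 1 rose when adjusted over the list alone. DUSP6 fell by 1.86, ETV5 by 1.24, PHLDA1 by 1.22 and DUSP4 by 1.22. The list lay below the other genes with a preset correlation (adjusted p = 8.61e-10) and had adjusted p = 0.628 with an estimated correlation. Of 7 EGF receptor ligands and receptors 1 fell, EREG (epiregulin) by 1.17, and 4 fell when adjusted over the list alone (preset correlation adjusted p = 0.0194, estimated correlation adjusted p = 0.628). The call with a preset correlation was lost with no filter and with the mean of all probe sets, where the median of the list was -0.15 against the reported -0.58. Of 13 cytokine genes 4 rose and 2 fell, also when adjusted over the list alone, and the 2 were IL1B (1.31) and IL1A (1.19). Of 16 interferon-stimulated genes 3 rose, among them RSAD2 by 1.72 and XAF1 by 1.10, and 8 rose when adjusted over the list alone (preset correlation adjusted p = 7.98e-08, estimated correlation adjusted p = 0.628). The cell cycle list had a median of -0.33 with 1 of 40 genes past the threshold, CDT1, which fell by 0.73, and 1 when adjusted over the list alone (preset correlation adjusted p = 6.55e-10, estimated correlation adjusted p = 0.628). Under alternative processing CDT1 passed in 1 of 7 settings, ETV5 in 1 of 6, RSAD2 in 2 of 7, IL1A and IL1B in 4 of 7, XAF1, PHLDA1 and DUSP4 in 5 of 7 and EREG in 5 of 6. Without passing, ETV5 had a log2 change of -0.58 with a floor of 50, and IL1A and XAF1 had -0.60 and 0.72 with the mean.

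Members of other lists also changed. CDKN2B rose by 1.34, and of the SMAD-induced genes 5 of 29 rose, BAMBI by 2.20, MMP13 by 2.55, with 1 LacZ signal set to the floor, and TAGLN by 1.62 among them. MMP1 and MMP9 fell by 1.41 and 1.31, so that the protease list had 3 up and 2 down of 17. Of 18 matrix genes 3 rose, among them COL5A1 by 1.22 and the collagen gene COL3A1 by 2.63 against LacZ signals set to the floor (adjusted p = 0.00123). COL3A1, also a marker of fibroblasts, had signals of 107.2 and 144.1 with HRAS N116Y and was below the floor on all 4 LacZ and HRAS G12V arrays. It passed in 6 of 6 alternatives, with a log2 change of 1.31 at a floor of 50. In the reported fit its residual reflects only its 2 HRAS N116Y signals, so its p-value is less firm. The alternatives reuse these signals and are no independent support. COL1A1, the other fibroblast marker measured, had a log2 change of 0.40 (adjusted p = 0.509). Of 10 mesenchymal genes 2 rose and 1 fell (HMGA2 with -1.03), and 1 of 9 integrin genes fell, ITGA6 by 1.17. STARD4, HMGCS1 and SQLE, the 3 of 12 cholesterol genes that passed, fell by 0.80, 0.72 and 0.60, and 7 fell when adjusted over the list alone; HMGCS1 and SQLE passed in 1 of 7 alternatives and STARD4 in 5. Camera with a preset correlation called the cholesterol list down (adjusted p = 4.26e-05) and the matrix (adjusted p = 0.00173) and histone lists (adjusted p = 0.000219) up, each with adjusted p = 0.628 with an estimated correlation, and the matrix list lost its call with the mean of all probe sets (median 0.11 against 0.17). IVL rose by 1.83 and SPRR1B fell by 1.46 in a differentiation list with 2 up and 2 down of 13. AKR1C2 and AKR1C1 fell by 1.15 and 0.89 in an oxidative stress list of 10, NT5E fell by 1.70 and RBMS3 and TGFB2 rose by 1.30 and 1.13 among 13 YAP and TAZ targets, and BMP4 fell by 1.20 and WNT10A rose by 0.79 among 12 BMP and WNT genes. Under alternative processing ATF3 passed in 1 of 6 settings, MMP13 and WNT10A in 2 of 6, RBMS3 in 2 of 5, TGFB2 in 2 of 7, VEGFA in 3 of 7, COL5A1, MMP1, MMP9, AKR1C2 and NT5E in 4 of 7, BMP4, HMGA2 and AKR1C1 in 4 of 6, CDKN2B in 5 of 7 and IVL, SPRR1B, ITGA6 and TAGLN in 6 of 7. With a floor of 50 BMP4 had a log2 change of -0.30, COL5A1 0.59, MMP9 -0.82 and RBMS3 0.69, and none of these 4 passed. The p63 list had 2 up and 1 down of 20, the mutant p53 list 1 up and 2 down of 14, and the wild-type p53, junction, Notch, glycolysis, BCL2, histone, ribosomal protein, keratin and TGF-beta-repressed lists had 0 past the threshold over all genes. The hypoxia list had 1 down of 14 (VEGFA with -0.68), the endoplasmic reticulum stress and immediate early lists had 1 up each (ATF3 by 0.84), the TGF-beta pathway list had 1 up of 16 (TGFB2) and the RAS list 1 down of 7 (HRAS). Adjusted over the list alone, the rising and falling genes numbered 7 and 1 for the SMAD-induced list, 5 and 2 for proteases, 6 and 0 for matrix, 4 and 2 for mesenchymal, 0 and 1 for integrin, 2 and 4 for differentiation, 0 and 2 for oxidative stress, 2 and 1 for YAP and TAZ, 1 and 3 for BMP and WNT, 6 and 1 for p63, 1 and 3 for mutant p53, 2 and 1 for CDK inhibitor, 1 and 2 for hypoxia, 2 and 0 for TGF-beta pathway and 0 and 1 for RAS genes. They numbered 1 and 0 for the endoplasmic reticulum stress, immediate early and basal keratin lists, 5 and 0 for histone, 3 and 0 for TGF-beta-repressed, 2 and 1 for simple keratin and 1 and 1 for Notch genes.

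In all, 142 genes rose and 76 fell with HRAS N116Y of 8981 tested by limma, 87 and 35 of them at least 2-fold. In single pairs of arrays 104 genes were at least 2-fold higher and 65 lower without TGF-beta3, and 271 and 142 with it. Without the filter on dim genes the fit called 9 rising and 3 falling genes, and the mean of all probe sets gave 47 and 26. Of the 55 genes called in this contrast among those named by the rule, 7 passed in every such alternative that tested them. A further 35 failed in at most 50% of these alternatives and 13 failed in most. CCL2, CCL5 and DUSP6 passed in 6 of 7, with adjusted p in limma's test up to 0.0502, 0.0988 and 0.0502. The HRAS G12V and HRAS N116Y contrasts share the LacZ arrays, and their correlation across genes was 0.005 where unchanged groups simulated against those arrays gave 0.5 (covariance 0 against 0.019).

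Active and dominant negative RAS were also compared directly, with no LacZ array between them. Of 19 RAS-MAPK output genes 10 were higher with HRAS G12V and 1 was lower past the threshold, with DUSP6 at 2.37 (SE 0.17, adjusted p = 5.72e-05), EGR1 at 1.98, PHLDA1 at 1.44 and DUSP4 at 1.31 on the log2 scale. HBEGF, EREG, NRG1 and TGFA, the 4 of 7 EGF receptor genes that passed, were higher by 1.70, 1.26, 1.10 and 0.70, and passed in 4 of 6, 5 of 6, 6 of 7 and 5 of 7 alternatives. With the mean of all probe sets NRG1 had 0.32 and TGFA 0.47, past no threshold, and the median of the list was 0.21 against 0.70, which ended its call with a preset correlation (reported adjusted p = 0.0179, and 0.603 with an estimated correlation). CCL2 and CCL5 were lower with HRAS G12V (-4.24 and -3.28), as were BAMBI (-2.75), TAGLN (-2.45) and CDKN2B (-2.19), while IL1B was higher (2.23). Of 40 cell cycle genes 9 were higher, BUB1 by 0.75, and 30 when adjusted over the list alone. Of 16 interferon-stimulated genes 5 were lower, with XAF1 at -1.87 and RSAD2 at -1.40, and 11 were lower and 1 higher when adjusted over the list alone. Adjusted over the list alone, 12 MAPK genes were higher and 1 lower, and 4 EGF receptor genes were higher and 1 lower. In all, 232 genes were higher with HRAS G12V and 341 lower. Camera with a preset correlation called 11 of 33 lists, 7 up and 4 down, among them the MAPK, cell cycle and interferon lists (adjusted p = 1.21e-08, adjusted p = 2.76e-14 and adjusted p = 9.18e-06), and 0 with an estimated one (adjusted p = 0.603, 0.715 and 0.715 for these 3). The cholesterol (median 0.35), endoplasmic reticulum stress (0.35), ribosomal protein (0.29) and oxidative stress (0.15) lists were also called up, and the histone (-0.77), CDK inhibitor (-0.74) and matrix (-0.38) lists down, with adjusted p from 0.603 to 0.769 with an estimated correlation. The ribosomal protein median was 0.02 under quantile normalization, where that call was lost; the oxidative stress list passed in 3 of 6 alternatives, the CDK inhibitors in 4 and the matrix list in 5. The cholesterol median was 0.17 with the mean of all probe sets, the CDK inhibitor median -0.27 with no filter, and the oxidative stress median ran from 0.07 to 0.24. Without the filter on dim genes 40 genes were higher and 95 lower. With the mean of all probe sets EGR1 had 1.28, past no threshold, and XAF1 -1.16, and BUB1 passed in 4 of 6 alternatives. Of 71 named genes that passed, 22 did so in every such alternative that tested them. Another 6 failed in most, among them EGR1 (3 of 7 passed, adjusted p from 0.0333 to 0.189) and RSAD2 (1 of 7, adjusted p from 0.0465 to 0.203).

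The response to TGF-beta3 was then set against that of LacZ cells for each RAS vector, as a difference of log2 ratios over 4 arrays with no test. With HRAS G12V, the mitochondrial tyrosyl-tRNA synthetase gene YARS2 had a log2 response of -0.04 where LacZ had -1.80, CLDN4 (claudin-4) 1.75 where LacZ had 0.38, and CCS, DDX54, PNRC1 and TADA3 had responses larger by 1.58 to 1.42. EEF2KMT had a response of -2.58 where LacZ had -0.56, and PBX2, ATAD5, PITPNA-AS1, ITPR2 and CACNG4 had differences of -1.50 to -1.33; another probe set of ITPR2 differed in direction. The median difference was 0.38 for the cytokine list (percentile 99.98 of random lists), 0.33 for each of the RAS-MAPK output and cholesterol lists, 0.30 for integrins and 0.29 for genes linked to mutant p53 (each at percentile 100). It was 0.24 for proteases (percentile 99.7), 0.17 for hypoxia (percentile 99.61) and 0.09 for cell cycle genes (percentile 98.06), and -0.27 for Notch genes (percentile 0.92) and -0.45 for ribosomal protein genes (percentile 0). The ribosomal protein list lost its call under quantile normalization in each contrast above that called it. Its difference of response was not computed under that normalization. In all, 65 genes had a response larger by at least 1 and 53 smaller, and the mean of all probe sets gave 27 and 21.

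With HRAS N116Y, the calcium-binding protein gene CALB1 had a log2 response to TGF-beta3 of -2.70 where LacZ had 0.86, and AGR2 -2.15 where LacZ had 0.33. EGR1 had a response of -0.19 where LacZ had 1.88, PRSS3 -0.44 where LacZ had 1.60, and APCDD1 and FAM83A had 0.01 and 0.07 where LacZ had 1.65 and 1.70. MXRA5, SLC27A2, MALAT1, EFS and LINC02551 had responses larger by 2.24 to 1.98, and the interferon-stimulated gene IFIT3 had -0.12 where LacZ had -2.24. The interferon list had a median difference of 0.63 (percentile 100), with 7 of 18 genes larger by at least 1, and the cell cycle list one of -0.54 (percentile 0), with 7 of 40 smaller by at least 1. Cytokine genes (0.31, percentile 98.63) and CDK inhibitors (0.46, percentile 97.71) lay higher, and endoplasmic reticulum stress genes (-0.31, percentile 0.56) and RAS genes and regulators (-0.42, percentile 1.51) lower. In all, 217 genes had a larger and 180 a smaller response. The mean of all probe sets gave 72 and 87.

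The last question was what differed between the arrays labelled p53 siRNA and control siRNA, whose labels were not checked by a measurement here. TCN1, a vitamin B12 binding protein, had a signal of 304.6 with p53 siRNA against 32.0 with control siRNA (log2 ratio 3.25), and HMGA2, a chromatin protein, 2168.1 against 270.6. HRAS had a log2 ratio of -0.29. SYT14, GPAT3, ADAM19, SOX9, FST (follistatin) and HAS2 had log2 ratios from 2.96 to 2.34. S100A8, a calprotectin subunit, had 33.9 against 569.7 (-4.07) and TMT1A 73.2 against 805.9 (-3.46), and P2RY6, TRIM22, MX1, LCN2, VGLL1 and MALAT1 had log2 ratios from -3.38 to -2.61.

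RAS-MAPK output genes were higher on the p53 siRNA array, with a median log2 ratio of 0.99 (percentile 100 of random lists) and 8 of 16 at least 2-fold higher. DUSP4 had 1.97, DUSP6 1.93, MYC 1.90 and ETV5 1.86. Of 7 EGF receptor ligands and receptors 5 were at least 2-fold higher (median 1.19, percentile 100), including NRG1 (1.56), TGFA (1.41) and EGFR (1.26). Of 11 BMP and WNT genes 5 were 2-fold higher and 1 lower (median 0.83, percentile 100), with DKK1 at 1.39. Of 21 interferon-stimulated genes 13 were at least 2-fold lower (median -1.06, percentile 0), IFIT2 at -2.39, IFI6 at -2.04 and XAF1 at -2.02 among them. As with every ratio of this pair, a fall with p53 siRNA cannot be told from a rise with control siRNA. Of 5 histone genes 3 were at least 2-fold lower (median -1.32, percentile 0.03), with H1-2 at -1.62. Hypoxia-induced genes had a median of 0.38 (percentile 99.28), with ANKRD37 at 1.39.

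The 24 targets of wild-type p53 had a median of -0.16 (percentile 7.74), 2 of them at least 2-fold higher and 3 lower; TP53INP1 had -2.17, CCNG1 -1.45 and RRM2B -1.28, while GADD45A, a growth arrest gene, had 1.54. Of 13 differentiation genes 5 were 2-fold lower and 1 higher, IVL at -2.59, with a list median of -0.23 (percentile 8.25). Of 14 cytokine genes 3 were 2-fold higher (IL1B at 2.11, CXCL8 at 1.84) and 4 lower (CCL5 at -1.88, IL6 at -1.41), with a median of -0.20 (percentile 12.05). Of 41 cell cycle genes 4 were 2-fold lower, BIRC5 at -1.34, with a median of 0.03 (percentile 16.31). The SMAD-induced, TGF-beta-repressed, p63, mutant p53, YAP, Notch, cholesterol, glycolysis, matrix, junction, CDK inhibitor, RAS, TGF-beta pathway, simple keratin and ribosomal protein lists had medians between -0.36 and 0.24, at percentiles from 9.07 to 89.14. The lists of mesenchymal genes (0.38, percentile 97.18), integrins (0.36, percentile 95.62), proteases (0.27, percentile 94.8) and BCL2 genes (0.30, percentile 94.92) lay higher, and those of endoplasmic reticulum stress (-0.13, percentile 5.74), oxidative stress (-0.12, percentile 4.67), basal keratins (-0.19, percentile 4.74) and immediate early genes (-0.24, percentile 6.26) lower.

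Of the markers of other cell types, MITF of melanocytes had 131.2 against 64.4, and HLA-DRA of leukocytes had 53 with control siRNA and a signal below the floor with p53 siRNA.

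In all, 213 genes were at least 2-fold higher and 558 lower of 9062 measured on the pair of siRNA arrays, a difference with no replicate check. The mean of all probe sets gave 117 and 318.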

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

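The tests in this part were all chosen after the values they concern had been seen, except the count of splits of the samples.

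Among control probe sets outside the gene measurements, those of a spike-in and of rRNA gave signals on the siRNA arrays far above those on the adenovirus arrays. The dap poly-A spike-in read 1001.9 with control siRNA and 1172 with p53 siRNA, against at most 6.1 on the 6 adenovirus arrays, and the 18S rRNA 5' probe set read 5872.7 and 7042.9, against at most 46.4. The cre hybridisation control did not stand apart, at 7409.6 and 7708.5 against 5075.3 to 8529.

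Another 4 values concern TGF-beta responses that were at least 2-fold in opposite directions with HRAS N116Y and with LacZ, a difference that was not tested as each rests on 2 pairs of arrays. MXRA5 differed by 2.24 on the log2 scale, higher with HRAS N116Y, with signals from 118.4 to 820.7. The other 3 differences are bounds, since 1 signal of each gene was below the floor of 20 and the rest were at most 84.1. GDPD3 was lower with HRAS N116Y by a difference of -2.15 or beyond and LINC01089 by one of -2.20 or beyond, and PECR was higher by at least 2.47. GDPD3, LINC01089 and PECR were named after their values were seen.

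HRAS was lower on all 4 arrays labelled with an HRAS vector. As the gene was named before the data were examined, its unadjusted p in limma's test is the test of a chance spread between these arrays, and its highest value over both contrasts and all settings, 0.000103, argues against that. This highest value came from HRAS G12V with no filter on dim genes, where the log2 change stayed at -1.64 but the adjusted p was 0.398 (range over 7 alternatives 0.0127 to 0.398, and 0.000264 to 0.0324 for HRAS N116Y). Both contrasts share the 2 LacZ arrays. The gene had 1 probe set, and no probe sequence was used, so a probe set outside the sequence carried by the vector stays open. Lower expression of the cells' own HRAS with either vector may account for it, as an untested hypothesis.

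The label fields that disagree on TGF-beta were weighed against genes that TGF-beta induces. If the titles carried the wrong state, the SMAD-induced list would be lower on the arrays titled with TGF-beta. The lowest of its medians in the 3 vectors was 1.505, at percentile 100 of random lists, which argues against wrong titles. No biological explanation was tested, since the fields concern labels.

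The 3033 genes called in the TGF-beta contrast were set against the other splits of the 6 arrays into 3 and 3. The real split was the 1 of 10 splits with as many genes, and the highest other called 0. These 10 splits are too few for a share under 0.05. In the fits of the other splits the TGF-beta3 difference also falls, at least in part, into the residual spread, which lowers their counts. Their 0 calls therefore cannot tell a TGF-beta3 effect from chance.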

How the results depend on the processing

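Each alternative changed 1 choice, and the fit of the 4 arrays for HRAS G12V against HRAS N116Y was chosen after the data were seen. Of 190 counts of genes under an alternative, 124 stayed within 1.5 times the reported count. For single genes and list medians, 4030 of 4463 values kept their direction and call or moved by less than the residual spread, 309 kept the direction but no longer passed, 8 passed newly, 114 moved and 2 turned. The 2 were medians of the ribosomal protein list under quantile normalization, -0.052 with TGF-beta3 and -0.013 with HRAS G12V. The 4030 include genes that passed in neither setting and genes that still passed with a much smaller change. Of the called genes named above, 102 of 119 passed in every alternative that tested them for TGF-beta3. They numbered 0 of 4 for HRAS G12V against LacZ, 7 of 55 for HRAS N116Y against LacZ and 22 of 71 between the RAS vectors. With a floor of 10 all counts stayed within 1.5 times. No paired analysis was possible because the labels give no replicate numbers, other than pairing by vector, which the reported fit has as its block. Signals under 50 limit what dim genes can show.

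Below, counts are higher then lower unless a direction is named. For HRAS G12V against LacZ over both TGF-beta states, the 4 falling genes became 2 under quantile normalization, 1 with a floor of 50, 0 with no filter, 2 with a filter of 100, 2 with the mean of all probe sets and 2 without the trend, while the fit of 4 arrays called 107 and 104. For HRAS N116Y against LacZ the falling genes were 50 with a floor of 50, and the counts were 9 and 3 with no filter, 47 and 26 with the mean, 75 and 32 without the trend and 287 and 157 in the fit of 4 arrays. For HRAS G12V against HRAS N116Y they were 40 and 95 with no filter and 71 and 148 with the mean, and the higher genes were 109 without the trend and 356 in the fit of 4 arrays.

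For TGF-beta3 over the vectors, leaving out 1 vector's pair of arrays gave 975 to 1853 rising and 1058 to 2132 falling genes, and the fit without a block 953 rising. Without the LacZ pair 2019 of the 3033 genes were called again, without the HRAS G12V pair 1937 and without the HRAS N116Y pair 2827. With the mean, the higher genes were 228 with LacZ, 311 with HRAS G12V (lower 253) and 244 with HRAS N116Y.

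For single pairs of HRAS G12V and LacZ arrays the counts without TGF-beta3 were 3 and 10 with a floor of 50 and with a filter of 100, 25 and 37 with no filter and 5 and 13 with the mean. With TGF-beta3 they were 10 and 12 with a floor of 50, 9 and 12 with a filter of 100, 39 and 47 with no filter and 8 and 18 with the mean. For HRAS N116Y without TGF-beta3 the higher genes were 67 with a floor of 50 and with a filter of 100, and 65 with the mean (lower 32); with TGF-beta3 the mean gave 129 and 89. For p53 siRNA the mean gave 117 and 318. The difference of response with HRAS G12V had 27 and 17 genes with a floor of 50, 108 and 95 with no filter, 26 and 19 with a filter of 100 and 27 and 21 with the mean. That with HRAS N116Y had 93 smaller with a floor of 50, 144 and 97 with a filter of 100 and 72 and 87 with the mean. The filters change the number of genes tested, and the mean takes in dim probe sets of a gene. For the other changes of count the cause was not tested.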

Other observations

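The changes with p53 siRNA ran opposite to those with HRAS N116Y, although the 2 comparisons share no array. Across 8526 genes measured in both, which are not independent replicates, Pearson's r was -0.329 and Spearman's rho -0.268. The relation was near 0 for HRAS G12V against LacZ (r = -0.004) and for TGF-beta3 (r = -0.008). The HRAS G12V changes had an SD of 0.229 across genes against a median SE of 0.172. Noise thus pulls their r towards 0, and it cannot show that no relation exists. Of 129 genes that rose with HRAS N116Y, 50 were at least 2-fold lower with p53 siRNA, where independent lists give 6.7, and 1 was at least 2-fold higher (3 expected). Of 68 genes that fell, 21 were at least 2-fold higher, where independent lists give 1.6, and 2 were lower (3.6 expected).

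Genes that rose with HRAS N116Y and were lower with p53 siRNA included TMT1A (2.37 and -3.46 on the log2 scale), IVL, the cornified envelope protein involucrin (1.83 and -2.59), CCL5 (3.27 and -1.88) and XAF1 (1.10 and -2.02). Genes that fell with HRAS N116Y and were higher with p53 siRNA included HAS2 (-1.81 and 2.34), DUSP6 (-1.86 and 1.93), DUSP4 (-1.22 and 1.97), ETV5 (-1.24 and 1.86) and IL1B (-1.31 and 2.11), of which DUSP6, DUSP4 and ETV5 belong to the RAS-MAPK output list.

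Of the tests of this opposition, 3 were chosen before their results were seen and the one on shared genes after, and the opposition itself was noticed in the named genes first. With a trend on signal taken out of both changes the correlation was -0.313, which argues against signal-dependent scaling. Over the 8142 genes in none of the gene lists it was -0.311, so the lists alone do not account for it, although interferon-stimulated genes outside the list remain among these, and with the HRAS N116Y pair that showed it less it was -0.22, so it does not rest on 1 HRAS N116Y pair. On the siRNA side every value rests on 1 pair of arrays, but 71 genes were shared in opposite directions where independent lists give 8.3, and 3 in the same direction where they give 6.5, which argues against gene-by-gene noise of that pair. Effects of p53 loss or of RAS signalling, cell density or another difference between the 2 siRNA cultures, and effects of either siRNA itself, the control siRNA included, stay open. None of these was tested.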
